A study of Homo sapiens with 9 samples.

How the data were processed

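RNA abundance was measured in A549 cells, an established human line derived from a lung adenocarcinoma, 72 h after transfection with small interfering RNA (siRNA). The 3 groups were cells given siRNA against FAM210B, siRNA against UQCRC2 and a negative control siRNA, with 3 arrays each, 9 in all. Per the labels, the siRNAs were mixtures. The siRNA sequences and the results of the authors' own PCR check of the knockdown were not used here. Arrays were assigned to groups and replicate numbers from the sample titles.

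Per the labels' protocols, total RNA was made into biotin-labelled cDNA and hybridised to Affymetrix whole-transcript arrays. The deposited table holds log2 signal values made by the authors with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, forces the same distribution of probe signals on every array and combines the probes of a transcript cluster into 1 value. This step can compress small differences of weak transcripts, and it removes shifts that are common to all genes of an array. The software, the annotation and the set of arrays normalized together are not given in the sources used here. The table has 67528 rows and no missing values. After RMA the array medians still ranged from 4.20 to 4.40 on the log2 scale. Arrays have no counting depth, so the number of arrays limits the precision.

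Rows were named from a platform annotation table, and symbols were brought up to date with RefSeq gene records of assembly GRCh38.p14, used for names and gene types only. Exactly 1 gene symbol was found for 23781 rows, several symbols for 1543 and no symbol for 42204. Of the 23781 symbols, 21497 were matched by Entrez identifier, 1974 by symbol and 306 by a synonym, and 4 were kept as they were. These rows covered 22411 genes. Of them, 528 had more than 1 row, and the row with the highest mean over the 9 arrays was kept. Genes were tested when that mean reached 4.25, the median of all row means, which left 15964 genes, 13447 of them protein coding. Rows with several symbols or none were tested apart and are not named.

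Group means were compared with linear models in limma 3.58.1 under R 4.3.3, with lmFit and eBayes at default settings. All 9 arrays entered 1 fit without covariates, which left 6 residual degrees of freedom. A gene is called changed when its Benjamini-Hochberg adjusted p was under 0.05 in a comparison, and adjusted p-values of single genes are limma's throughout. Log2 fold changes are differences of group means with limma's standard error (SE). An F test over the 3 groups was added. Single genes were also compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 arrays is 0.1.

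In all, 37 gene lists with 991 distinct members, fixed before the data were examined, covered mitochondrial, metabolic, stress, adhesion, signalling, cell cycle and cell type marker genes. The targeted gene of a comparison was left out of its lists. Of the 37, 36 had the 5 tested members required, and the 13 mitochondrially encoded genes had no row with a single symbol, so they were not tested. Lists were tested with camera at an inter-gene correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. The p-values of these fixed lists were adjusted over the 36 lists.

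Genes to be named were also fixed before the data were examined. They are FAM210B, UQCRC2, FAM210A and PDK4, then the 8 protein-coding genes with the largest positive and the 8 with the largest negative change among called genes without overlap between the groups, then up to 4 members with the smallest p of each list. Other genes are said to be chosen after their values were seen.

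The comparisons of both knockdowns share the control arrays. Unchanged groups were therefore simulated 100 times with residuals correlated between genes as observed, and expected overlaps of independent lists were computed. The 3 control arrays cannot be split into parts of 2 or more.

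The fit was tested on simulated data with the real gene means and residual SDs, drawn independently for each of the 15964 genes, in which 67 genes were changed by 0.3 on the log2 scale, 67 by 0.6 and 66 by 1. For si-FAM210B against control it called 32.8% of the genes changed by 0.3, 79.1% of those changed by 0.6 and 93.9% of those changed by 1. For si-UQCRC2 against control these shares were 29.9%, 79.1% and 93.9%, and for si-FAM210B against si-UQCRC2 28.4%, 73.1% and 97.0%. Of the genes called, 6.67%, 6.83% and 5.73% were false in the same order. A list moved by -0.3 was called in each of the 3 comparisons, and 1 unmoved list was called in the first. The draws gave a gene the same SD in all groups and held no correlated genes and no deviating arrays. They therefore do not measure the error rates in the real data.

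The alternatives tried were no filter on low values, a stricter filter on row means, quantile normalization and median centring of the deposited values, an intensity trend with robust eBayes, array weights, the replicate number as a block, the mean of all rows of a gene, a fit of only the groups compared, a minimum change of 1.5-fold, and each array left out in turn. Cyclic loess and leaving out si-FAM210B replicate 1 and control replicate 3 together were chosen after seeing the data.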

Results

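The series holds 9 expression arrays of A549 cells, 3 for each of si-FAM210B, si-UQCRC2 and the si-negative control, all taken 72 h after transfection. FAM210B encodes a mitochondrial membrane protein, and UQCRC2 encodes a core subunit of respiratory complex III. The design asks which transcripts differ once either RNA is targeted. The labels call the 3 arrays of a group biological replicates without saying whether the cultures were separate, so p-values measure the spread between these arrays. The median SD of a tested gene within a group was 0.130 for si-FAM210B, 0.0878 for control and 0.0379 for si-UQCRC2 on the log2 scale. On the first principal component, with 55.3% of the variance, si-FAM210B replicate 1 lay at -33.2 against -0.908 and -8.39 for the other si-FAM210B arrays. Control replicate 3 lay at -6.99 against 12.1 and 9.87 for the other controls. The deviations of these 2 arrays from their groups correlated across genes (r = 0.742), and for each comparison the number of called genes is also given without both.

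**Figure D1:**
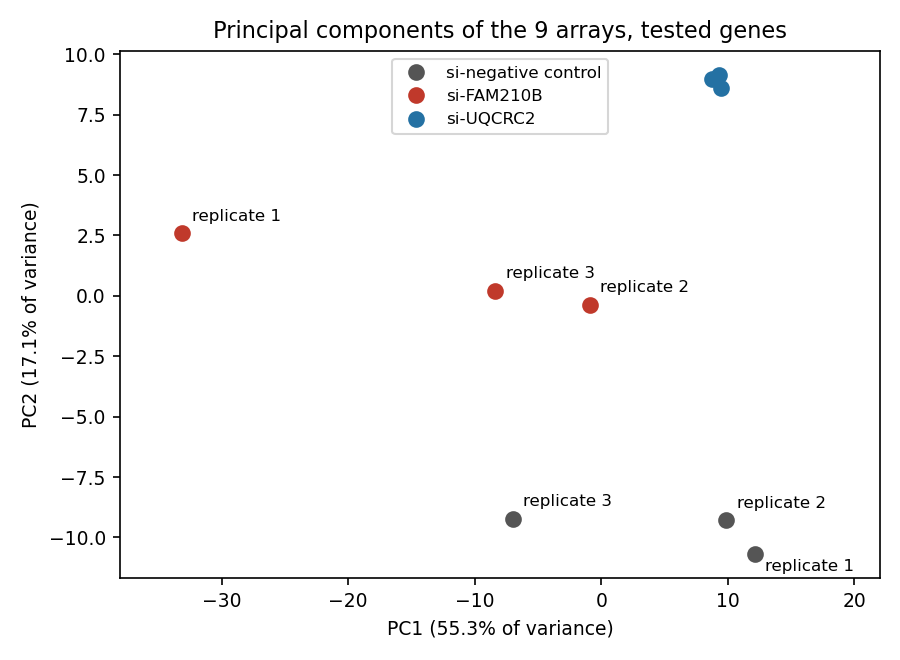
Each point is 1 array, placed by its scores on the first (x axis, 55.3% of variance) and second (y axis, 17.1%) principal components of the tested genes, coloured by siRNA. The si-UQCRC2 arrays lie together, while si-FAM210B replicate 1 at -33.2 and control replicate 3 at -6.99 lie to the left of their groups.

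UQCRC2 RNA fell clearly under its own siRNA, whereas FAM210B RNA differed little under its own. UQCRC2 was at 8.36 ± 0.01 (SD, n = 3) in si-UQCRC2 against 9.83 ± 0.13 in control, a log2 fold change of -1.47 ± 0.14 (SE, limma adjusted p = 0.000375). The exact permutation p for UQCRC2 was 0.1, the smallest that 3 against 3 arrays allow. FAM210B was at 6.27 ± 0.19 (SD, n = 3) in si-FAM210B against 6.44 ± 0.05 in control, which leaves 88.7% of the control signal. Its log2 fold change of -0.17 ± 0.09 (SE) did not pass (limma adjusted p = 0.239, exact permutation p = 0.4). FAM210B in si-FAM210B replicates 1 to 3 read 6.48, 6.10 and 6.22, and in the controls 6.39, 6.46 and 6.48. Replicate 1 thus reached the level of the controls, and FAM210B does not check the label of that array. Without replicate 1 the FAM210B change was -0.28 (adjusted p = 0.0251), and without replicate 2 it was -0.09. FAM210B in si-UQCRC2 differed from control by 0.02 ± 0.09 (SE, adjusted p = 0.984). FAM210A, a paralog of FAM210B, differed by -0.13 in si-FAM210B and -0.15 in si-UQCRC2, neither of which passed.

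**Figure D2:**
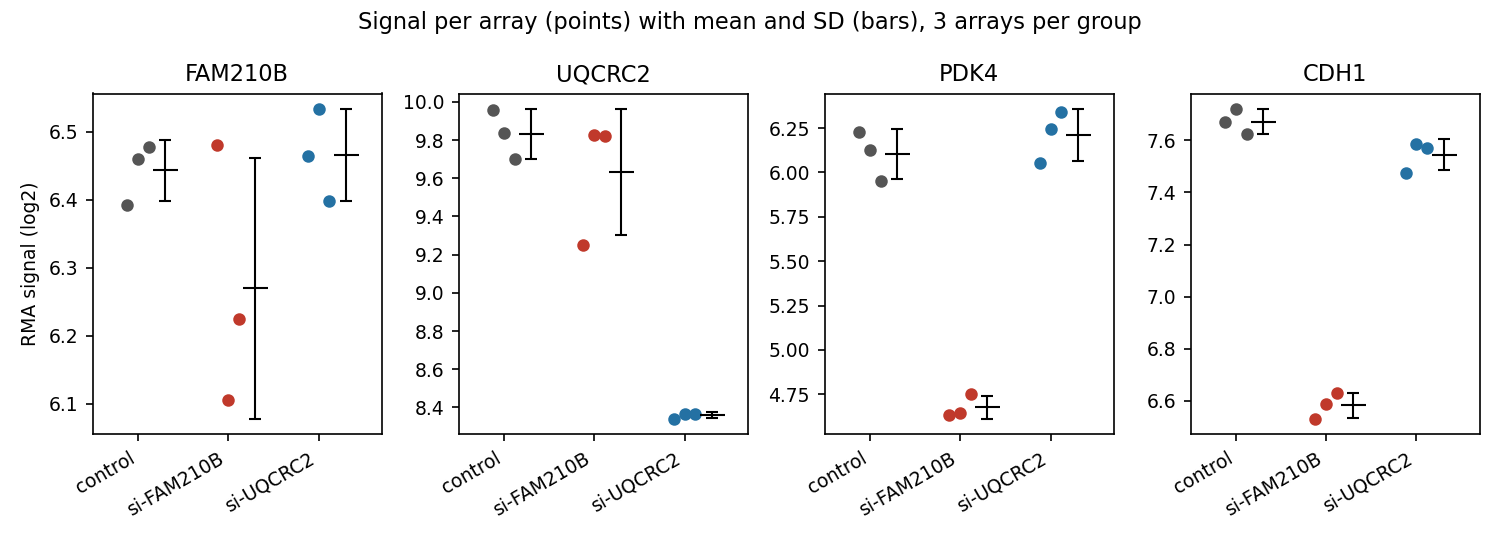
The y axes give RMA signal on the log2 scale for FAM210B, UQCRC2, PDK4 and CDH1, each with its own range that does not start at 0. Points are the 3 arrays of each group, and the bars beside them are mean and SD. UQCRC2 is at 8.36 in si-UQCRC2 against 9.83 in control, while for FAM210B 1 of the si-FAM210B arrays lies at 6.48 among the controls. PDK4 and CDH1 are lower in each si-FAM210B array than in any other array.

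Among rows with a single gene symbol, GREM1, a secreted antagonist of bone morphogenetic proteins, rose most in si-FAM210B cells. Its log2 fold change was 1.70 ± 0.11 (SE, n = 3 per group here and below). STC1, a secreted glycoprotein hormone, rose by 1.39 ± 0.09. MT2A, a metal-binding metallothionein with near-identical paralogs that probes may not separate, read 1.36 ± 0.09 higher. TGFB1I1, a focal adhesion protein, rose by 1.32 ± 0.08, TAGLN, an actin-binding protein of smooth muscle, by 1.18 ± 0.07, and SPARC, a matrix glycoprotein, by 1.03 ± 0.06. The largest decreases were in GPX2, a glutathione peroxidase (-1.50 ± 0.07), TM4SF20 (-1.49 ± 0.20), PDK4, a kinase that inhibits pyruvate dehydrogenase (-1.43 ± 0.09), and INHBB, a subunit of activin and inhibin (-1.40 ± 0.15). CDH1, the epithelial adhesion molecule E-cadherin, fell by 1.09 ± 0.06. PODXL (1.08) and ITGA11 (1.02) completed the 8 largest increases, and IFI30 (-1.22), PLA2G4A (-1.12) and CYP4F11 (-1.07) the 8 largest decreases. All 16 genes kept their call with each of the 9 arrays left out in turn.

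In si-FAM210B against control, 1002 of 15964 genes were called, 444 higher and 558 lower, of which 134 changed at least 1.5-fold and 18 at least 2-fold. Quantile normalization gave 533 higher and 427 lower, median centring 184 higher and 375 lower, and array weights 3905 higher and 3113 lower. A fit of only these 2 groups called 227 genes, 130 higher and 97 lower. The full fit pools the spread with the si-UQCRC2 arrays, which had the smallest median SD. Which direction held more calls thus depended on the processing. Groups did not overlap for 24.0% of genes, against an average of 10% over all divisions of these arrays. Genes on the same arrays are correlated, so a single division can lie far from that average. The share of other divisions was not computed, so an excess over chance cannot be read from it. Without both deviating arrays the count was 3889, 1792 higher and 2097 lower, among them 994 of the 1002. It was 1975 without si-FAM210B replicate 2, 479 without si-FAM210B replicate 3, 332 and 306 without control replicates 1 and 2, and 539, 533 and 531 without si-UQCRC2 replicates 1, 2 and 3, which only enter the estimate of the spread.

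The list of mesenchymal markers shifted up in si-FAM210B cells, and the lists of DNA replication, mitosis and histone genes shifted down, none of them with an estimated correlation. Of 25 mesenchymal markers tested, 10 rose and none fell (14 rose adjusted over the list alone), among them SPARC, TAGLN, ACTA2 (0.47 ± 0.05) and AXL, a receptor tyrosine kinase (0.44 ± 0.06). The list's shift passed camera (adjusted p = 2.04e-09; adjusted p = 0.130 with an estimated correlation), and 16 members rose without both deviating arrays. Of 24 epithelial markers, CDH1, ELF3 (-0.32) and JUP (-0.39) fell and none rose (5 fell and 1 rose adjusted over the list alone), but the list as a whole did not pass (adjusted p = 0.348), its median of 0.06 and mean of -0.05 differing in sign. Of 41 replication genes, 11 fell and none rose (24 fell adjusted over the list alone), among them CDC6 (-0.38), ORC1, a subunit of the origin recognition complex (-0.50), and POLA2, a subunit of DNA polymerase alpha (-0.41). Of 53 mitosis genes, 5 fell and none rose (21 fell adjusted over the list alone), among them the kinase AURKA (-0.46 ± 0.06) and the phosphatase CDC25B (-0.30). Of 17 replication-dependent histones, 4 fell (9 adjusted over the list alone), led by H2BC10 (-0.71 ± 0.11) and H2BC3 (-0.66 ± 0.13), which belong to a family of near-identical genes. The replication and mitosis shifts had camera adjusted p = 2.79e-11 and 9.16e-12 (both adjusted p = 0.443 with an estimated correlation), and histones 7.34e-06 (adjusted p = 0.240 with an estimated correlation). With the deviating pair left out, 26 replication genes, 27 mitosis genes and 8 histones fell.

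Among metabolic and stress lists in si-FAM210B cells, NRF2 targets, lipid synthesis genes and mitochondrial translation and folding genes shifted down. Of 23 NRF2 targets, which respond to oxidative stress, 5 fell and 1 rose (10 fell and 1 rose adjusted over the list alone). GPX2 and GCLC, which makes a glutathione precursor (-0.69 ± 0.09), fell, and HMOX1, the heme-degrading enzyme, rose by 0.42 ± 0.05. The NRF2 shift had camera adjusted p = 5.33e-05 (adjusted p = 0.443 with an estimated correlation). Of 20 cholesterol synthesis genes, STARD4 (-0.36) and HSD17B7 (-0.34) fell (10 adjusted over the list alone; camera adjusted p = 0.000539; adjusted p = 0.205 with an estimated correlation). Of 18 fatty acid synthesis genes, the desaturase SCD (-0.73 ± 0.12) and the regulator SREBF1 (-0.37) fell (4 adjusted over the list alone; camera adjusted p = 0.00933). MRPS9 (-0.27) and MRPS28 (-0.28) fell among 66 mitochondrial ribosomal proteins (2 also adjusted over the list alone; camera adjusted p = 0.000132), and HSPE1 (-0.27) and GRPEL1 (-0.22) among 18 mitochondrial chaperones and proteases (3 adjusted over the list alone; camera adjusted p = 0.00107). These 3 lists had adjusted p = 0.443 with an estimated correlation. With the deviating pair left out, 11 NRF2 targets fell and 2 rose, 9 cholesterol and 8 fatty acid synthesis genes fell, 9 mitochondrial ribosomal proteins fell and 1 rose, and 5 mitochondrial chaperones and proteases fell. Under a stricter level filter neither the cholesterol (adjusted p = 0.0654) nor the fatty acid synthesis shift (0.0569) passed.

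Weaker downward shifts in si-FAM210B cells covered pyruvate metabolism, protein folding and hypoxia genes. In the list of 14 pyruvate dehydrogenase genes, PDK4, PDK3 (-0.47) and DLAT (-0.36) fell, and PDP1, the activating phosphatase, rose by 0.40 ± 0.05 (4 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0433; adjusted p = 0.50 with an estimated correlation). HILPDA (-0.64 ± 0.07) and CA12 (-0.50 ± 0.07) fell among 20 HIF1 targets (3 adjusted over the list alone; camera adjusted p = 0.0433), PDIA4 (-0.29) among 18 endoplasmic reticulum chaperones (4 adjusted over the list alone; camera adjusted p = 0.0188), and GDF15 (-0.62 ± 0.15) among 38 genes of the integrated stress response (0 adjusted over the list alone; camera adjusted p = 0.00945). These 3 lists had adjusted p = 0.443 with an estimated correlation. The proteasome list had a median of -0.14 over 28 subunits with no member called by limma over all genes or over the list alone (camera adjusted p = 0.00193; adjusted p = 0.635 with an estimated correlation). Without si-FAM210B replicate 1, the shifts of the pyruvate dehydrogenase, chaperone, HIF1 and proteasome lists did not pass (adjusted p = 0.10, 0.135, 0.135 and 0.480). Without control replicates 1 or 2 neither pyruvate dehydrogenase genes (0.0629 and 0.0566) nor HIF1 targets (0.0515 and 0.0633) passed. These 4 and the integrated stress response did not pass after quantile normalization (adjusted p = 0.0691, 0.0862, 0.158, 0.0719 and 0.0673) or cyclic loess, nor under a stricter level filter (0.395, 0.105, 0.224, 0.0516 and 0.147), nor did NRF2 targets after cyclic loess (0.0646). The HIF1 and chaperone shifts also failed without both deviating arrays (adjusted p = 0.0583 and 0.0554).

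The lists of inflammatory genes, near the threshold, and of markers of other cell types shifted up in si-FAM210B cells. Of 20 NF-kappaB and inflammatory genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0498; adjusted p = 0.50 with an estimated correlation). The chemokine CCL2 rose by 0.69 ± 0.07 and IRAK2 by 0.46 ± 0.06, and PTGS2, a prostaglandin synthase, fell by 0.90 ± 0.15. The inflammatory shift did not pass without si-FAM210B replicate 2 (adjusted p = 0.171), control replicates 1 or 3 (0.0515 and 0.0582), si-UQCRC2 replicates 1 or 2 (0.0533 and 0.0519) or both deviating arrays (0.0583), nor under either other level filter (0.0526 and 0.0533) or with the mean of all rows of a gene (0.0502). Of 7 tested markers of immune cells, endothelium and fibroblasts, CD68, a lysosomal protein of macrophages and other cells, rose by 0.70 ± 0.06 (2 rose adjusted over the list alone; camera adjusted p = 0.0110; adjusted p = 0.50 with an estimated correlation). Without si-FAM210B replicate 1 this shift had adjusted p = 0.0503, and without both deviating arrays 0.0296.

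The lists of respiratory complexes I, III, IV and V held no called gene in si-FAM210B cells. None of 31 complex I, 12 complex III, 10 complex IV and 15 complex V genes was called by limma over all genes or over the lists alone, and no shift passed (camera adjusted p = 0.0572, 0.266, 0.348 and 0.781). In the fit without the deviating pair, 3 complex I genes were higher and 5 lower, 1 complex III gene was higher and 2 lower, 4 complex V genes were higher and 1 lower, and no complex IV gene was called. The lists of p53 targets (adjusted p = 0.0592), TGF-beta response (0.0625) and cytosolic ribosomal proteins (0.0800) did not pass with all arrays, and all 3 passed upward without the deviating pair (adjusted p = 0.0200, 0.0200 and 0.00418). In the TGF-beta list 6 genes rose and 3 fell (7 and 3 adjusted over the list alone; 9 and 3 without the pair), with CCN2 at 0.87 ± 0.10 and SMAD6 at -0.54 ± 0.06. TP53I3 (0.55) and GADD45A (0.37) rose and GDF15 (-0.62) fell among p53 targets. Some genes changed in lists without a shift. The glucose transporter SLC2A3 (-0.88 ± 0.09) and PFKFB3 (-0.27) fell among glycolysis genes (adjusted p = 0.149). MMP2 (0.70 ± 0.07) was 1 of 4 invasion genes that rose, and HPSE (-0.34) fell (0.426). FOSL1 (0.65 ± 0.08) and JUNB (0.64) rose and NR4A1 (-0.42) fell among immediate early genes (0.240). ITGB5 (-0.43) fell and ITGA5 (0.38) rose among integrins and laminins (0.932), OAS1 (-0.44) fell among interferon-stimulated genes (0.682), and SDHD (-0.36) fell among citric acid cycle genes (0.140). ABCA3 (0.40) rose among alveolar markers (0.0630), and HMOX1 and SLC25A37 (0.34) rose and SLC11A2 (-0.42) and ABCB6 (-0.21) fell among genes of heme and iron (0.348). Of autophagy and lysosome genes, 4 rose, among them MAP1LC3B (0.34), and 2 fell, among them GLA (-0.49) (0.448). OPTN (0.34) and SQSTM1 (0.25) rose among mitophagy genes (0.959), and RPS12 (0.20) among cytosolic ribosomal proteins (0.0800). Fatty acid oxidation (0.682) and apoptosis regulators (0.682) held no called gene. Median and test differed in sign for epithelial markers, integrins, interferon-stimulated genes, apoptosis regulators (medians over 0, tests down) and mitophagy genes (median under 0, test up). By fry, epithelial markers (adjusted p = 0.0224), invasion genes (0.0182) and TGF-beta response (0.0157) passed, and mitochondrial ribosomal proteins (0.0709), endoplasmic reticulum chaperones (0.0709) and the proteasome (0.289) did not. The members ELF3, JUP, ORC1, CDC6, POLA2, CDC25B, H2BC3, STARD4, HSD17B7, SREBF1, MRPS9, MRPS28, HSPE1, GRPEL1, PDK3, DLAT, PDIA4, GDF15, PTGS2, GADD45A, SDHD, PFKFB3, HPSE, JUNB, NR4A1, SLC25A37, SLC11A2, ABCB6, GLA, SQSTM1 and RPS12 each lost their call when 1 or more single arrays were left out.

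**Figure D3:**
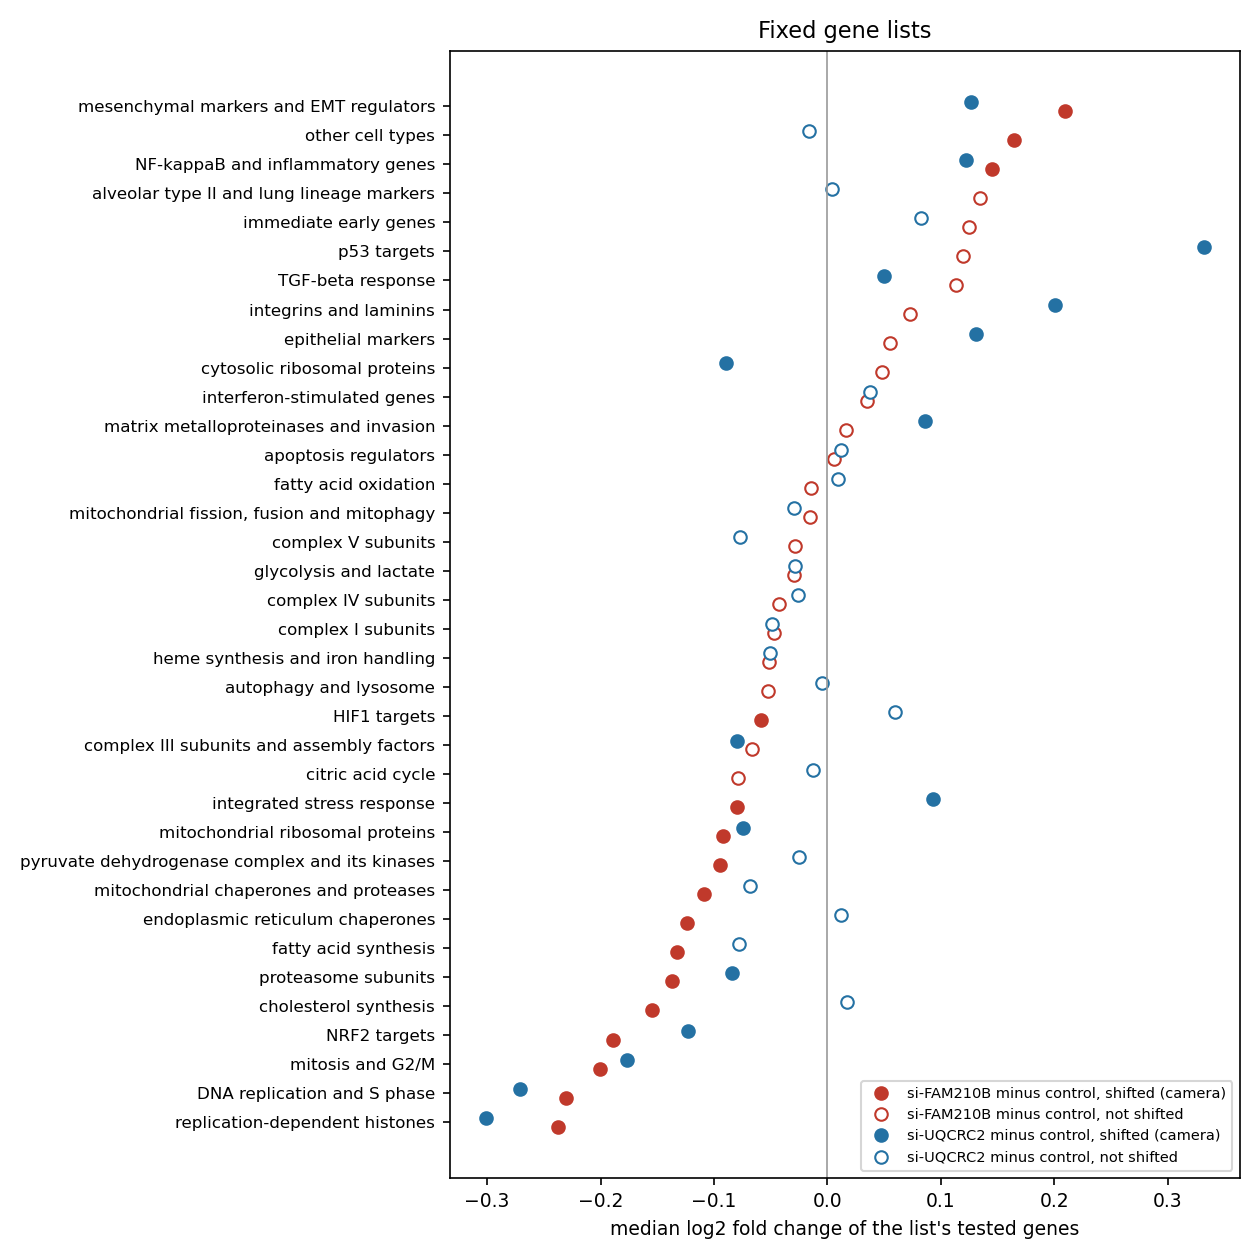
Each row is 1 of the 36 tested gene lists, and the x axis gives the median log2 fold change of its tested genes, red for si-FAM210B minus control and blue for si-UQCRC2 minus control. Filled points passed camera at the preset correlation and open points did not. Replication, mitosis and histone lists lie below 0 in both, and p53 targets lie at 0.33 in si-UQCRC2 and 0.12 in si-FAM210B.

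In si-UQCRC2 cells, TNFAIP6, a secreted protein that binds hyaluronan, rose most, by a log2 fold change of 1.89 ± 0.11 (SE, n = 3 per group). TP53INP1, a p53-induced gene, rose by 1.34 ± 0.15, DGKA, a diacylglycerol kinase, by 1.32 ± 0.06, CLTRN by 1.27 ± 0.08 and STC1 by 1.25 ± 0.09. Apart from UQCRC2 itself, the largest decreases were smaller than these increases, in the fatty acid hydroxylase CYP4F11 (-0.77 ± 0.06), F2RL2 (-0.75 ± 0.17), the non-muscle myosin MYH10 (-0.74 ± 0.07) and ARPC1A, a subunit of the Arp2/3 actin-nucleating complex (-0.71 ± 0.09). NEFL (1.18), MT2A (1.17, with the paralogs above) and NT5E (1.14) completed the 8 largest increases, and TESC (-0.65), HGD (-0.64) and DYNLT1 (-0.64) the decreases. Of these 16 genes, F2RL2 alone lost its call when single arrays were left out, for each si-UQCRC2 array and for control replicates 1 and 2 (adjusted p = 0.131 to 0.137).

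In si-UQCRC2 against control, 712 of 15964 genes were called, 482 higher and 230 lower, of which 119 changed at least 1.5-fold (103 higher) and 16 at least 2-fold. Groups did not overlap for 29.2% of genes, against an average of 10% over all divisions, with the limit given for si-FAM210B. Without both deviating arrays the count was 2736, 1314 higher and 1422 lower, and included all 712, and array weights gave 1943 higher and 2202 lower. It was 1654 without si-FAM210B replicate 1, which enters only the spread, 336, 296 and 471 without control replicates 1, 2 and 3, and 263, 249 and 253 without si-UQCRC2 replicates 1, 2 and 3.

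The list of targets of the tumour suppressor p53 shifted up and the cell cycle lists shifted down in si-UQCRC2 cells. Of 25 p53 targets, 11 rose and none fell (19 rose adjusted over the list alone), among them SPATA18 (0.65 ± 0.07), the death receptor FAS (0.56 ± 0.06), TP53INP1 and GADD45A (0.55 ± 0.07). This shift passed camera at the preset correlation (adjusted p = 1.28e-19) and with an estimated one (adjusted p = 0.0441). Of 41 replication genes, 11 fell (31 lower and 1 higher adjusted over the list alone), among them RRM2, a ribonucleotide reductase subunit (-0.38 ± 0.06), MCM5 (-0.32) and CHAF1A (-0.27). Of 53 mitosis genes, 12 fell (19 adjusted over the list alone), among them the transcription factor FOXM1 (-0.52 ± 0.07) and BIRC5 (-0.29). Of 17 histones, H2BC14 (-0.55 ± 0.07) and H2BC11 (-0.39) fell (8 adjusted over the list alone). The 3 shifts had camera adjusted p = 4.20e-18, 1.58e-14 and 8.73e-09 (adjusted p = 0.165, 0.279 and 0.0786 with an estimated correlation). With the deviating pair left out, 22 p53 targets rose and 34 replication and 39 mitosis genes fell.

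The lists of epithelial, mesenchymal and adhesion genes shifted up in si-UQCRC2 cells, the first also with an estimated correlation, while CDH1 read -0.13. Of 24 epithelial markers, 4 rose and none fell (7 rose adjusted over the list alone), with the keratin KRT19 at 0.73 ± 0.07 and MARVELD2 at 0.41. The epithelial shift passed with the preset (adjusted p = 1.53e-05) and an estimated correlation (adjusted p = 0.0441). Of 25 mesenchymal markers, 6 rose and 1 fell (10 and 1 adjusted over the list alone), with fibronectin FN1 (0.76 ± 0.10), TAGLN (0.68 ± 0.07) and SPARC (0.56 ± 0.06) rising (camera adjusted p = 1.19e-05; adjusted p = 0.101 with an estimated correlation). Of 13 integrins and laminins, 5 rose and none fell over all genes or over the list alone, among them ITGA2 (0.66 ± 0.11) and ITGA3 (0.40 ± 0.06) (camera adjusted p = 1.11e-06; adjusted p = 0.0786 with an estimated correlation). PLAUR, the urokinase receptor (0.56 ± 0.08), and TIMP1, an inhibitor of metalloproteinases (0.40 ± 0.05), rose among 14 invasion genes (2 also adjusted over the list alone; camera adjusted p = 0.00512; adjusted p = 0.122 with an estimated correlation). Of 20 TGF-beta response genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone), with TGFBR1 (0.56 ± 0.08) and BHLHE40 (0.47 ± 0.05) rising (camera adjusted p = 0.0414; adjusted p = 0.279 with an estimated correlation). NFKBIZ (0.48 ± 0.06) led 3 genes that rose of 20 inflammatory genes (8 adjusted over the list alone; camera adjusted p = 0.00107; adjusted p = 0.279 with an estimated correlation). The TGF-beta shift did not pass under a stricter level filter (adjusted p = 0.0571), without the deviating pair (0.0554) or without control replicate 1 (0.0913), control replicate 3 (0.0657) or si-UQCRC2 replicate 1 (0.0776).

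Stress genes moved in both directions in si-UQCRC2 cells. Of 38 integrated stress response genes, which ATF4 and CHOP induce, 4 rose and 1 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00337; adjusted p = 0.308 with an estimated correlation), among them WARS1 (0.28), SESN2 (0.33) and the mitochondrial folate enzyme ALDH1L2 (0.59 ± 0.14). Of 23 NRF2 targets, 5 fell and none rose (6 fell and 1 rose adjusted over the list alone), with OSGIN1 at -0.59 ± 0.08 and HMOX1 at -0.46 ± 0.05 (camera adjusted p = 1.19e-05; adjusted p = 0.332 with an estimated correlation). UQCC3, an assembly factor of complex III, fell by 0.29, the single call among 12 other complex III genes over all genes and over the list alone (camera adjusted p = 0.0414; adjusted p = 0.279 with an estimated correlation). The complex III shift did not pass without control replicate 1 (adjusted p = 0.118), control replicate 2 (0.0505), si-UQCRC2 replicate 1 (0.0633) or si-UQCRC2 replicate 3 (0.0669), nor after quantile normalization (0.0665) or cyclic loess (0.0708) or under a stricter level filter (0.257). MRPL24 (-0.28) fell among 66 mitochondrial ribosomal proteins and PSMC3 (-0.43 ± 0.06) among 28 proteasome subunits (0 and 2 lower adjusted over the list alone; camera adjusted p = 0.000351 and 0.00194; adjusted p = 0.400 and 0.615 with an estimated correlation). No cytosolic ribosomal protein was called by limma over all genes or over the list alone, and the median of 31 lay at -0.09 (camera adjusted p = 0.000428; adjusted p = 0.383 with an estimated correlation). Without control replicate 1 the proteasome shift did not pass (adjusted p = 0.0535).

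No shift passed in si-UQCRC2 cells for complexes I (camera adjusted p = 0.178), IV (0.676) and V (0.0993), which held no called gene over all genes or over the lists alone. PDP1 (0.51 ± 0.05) rose among pyruvate dehydrogenase genes (camera adjusted p = 0.676), where PDK4 read 0.11 ± 0.09. The lipid-activating enzyme ACSL4 (0.72 ± 0.11) rose among fatty acid oxidation genes (0.518), and OGDH (0.26) among citric acid cycle genes (0.646). SAMD9 (0.91 ± 0.09) led 3 interferon-stimulated genes that rose (list 0.133), WIPI1 rose and GLA (-0.42) fell among autophagy and lysosome genes (0.825), PMAIP1 (0.44) rose among apoptosis regulators (0.150) and CEACAM6 (0.70 ± 0.07) among alveolar markers (0.535). CD68 rose by 0.64 ± 0.06 among markers of other cell types (0.133), and OPTN (0.36) among mitophagy genes (0.751). SLC25A37 (0.32) rose and HMOX1 (-0.46) fell among heme and iron genes (0.190), DUSP6 (0.29) rose and NR4A1 (-0.45) fell among immediate early genes (0.170), and FASN (-0.36) fell among fatty acid synthesis genes (0.133). Glycolysis (0.751), mitochondrial chaperones (0.0519), endoplasmic reticulum chaperones (0.562), HIF1 targets (0.149) and cholesterol synthesis (0.191) held no gene called over all genes. The median lay under 0 and the test up for mitophagy, pyruvate dehydrogenase, citric acid cycle, glycolysis and autophagy genes and for markers of other cell types. Without the deviating pair, mitochondrial chaperones (adjusted p = 0.00362, 4 lower) and fatty acid synthesis (0.0311, 5 lower) passed downward and immediate early genes (0.0494, 6 higher and 3 lower) upward. By fry, interferon-stimulated genes (adjusted p = 0.000749) and apoptosis regulators (0.00392) passed, and mitochondrial ribosomal proteins (0.131) and the proteasome (0.291) did not. The members MCM5, CHAF1A, BIRC5, H2BC11, MARVELD2, WARS1, SESN2, ALDH1L2, UQCC3, MRPL24, OGDH, PMAIP1, SLC25A37, DUSP6, NR4A1, GLA and FASN each lost their call when 1 or more single arrays were left out.

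Compared directly, si-FAM210B cells had more DIO2, which activates thyroid hormone (log2 difference 1.34 ± 0.15, SE, n = 3 per group), more UQCRC2 (1.27 ± 0.14) and more of the focal adhesion protein ZYX (0.98 ± 0.12) than si-UQCRC2 cells. They had less TNFAIP6 (-2.16 ± 0.11), complement component C5 (-1.60 ± 0.11), GPX2 (-1.54 ± 0.07), PDK4 (-1.53 ± 0.09) and IFI30 (-1.51 ± 0.07). ARPC1A (0.93), ITGA11 (0.92), MYH10 (0.91), HMOX1 (0.88) and ADAM12 (0.85) completed the genes highest in si-FAM210B, and LIPH (-1.50), TSPYL2 (-1.42) and PTGS2 (-1.37) the lowest. All 16 kept their call with each array left out. In all, 1561 genes were called, 524 higher and 1037 lower in si-FAM210B, of which 209 differed at least 1.5-fold and 27 at least 2-fold. Median centring gave 212 higher and 951 lower, whereas array weights gave 3967 higher and 3035 lower. Groups did not overlap for 41.7% of genes, against an average of 10% over all divisions, with the same limit as above. Without both deviating arrays 3835 genes were called, 1760 higher and 2075 lower, among them 1556 of the 1561. The count was 3280 without si-FAM210B replicate 2, 947 without si-FAM210B replicate 3, and 571, 544 and 505 without si-UQCRC2 replicates 1, 2 and 3.

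The lists of p53 targets, epithelial markers and integrins lay lower, and that of mesenchymal markers higher, in si-FAM210B than in si-UQCRC2 cells. Of 25 p53 targets, 11 were lower (16 lower and 1 higher adjusted over the list alone), among them SESN1 (-0.65 ± 0.09), and of 24 epithelial markers 9 were lower (10 adjusted over the list alone), among them CDH1 (-0.96 ± 0.06) and EPCAM (-0.44 ± 0.06). Of 13 integrins and laminins 5 were lower (7 adjusted over the list alone), led by ITGA6 (-0.74 ± 0.09). Of 25 mesenchymal markers 7 were higher (10 higher and 2 lower adjusted over the list alone), among them the repressor SNAI1 (0.73 ± 0.13). Camera adjusted p-values were 6.35e-08, 0.000127, 0.000315 and 0.00202 (adjusted p = 0.188, 0.112, 0.188 and 0.227 with an estimated correlation). Of 38 integrated stress response genes 12 were lower and 3 higher (20 and 4 adjusted over the list alone), with PHGDH at -0.34 ± 0.05 and GDF15 at -0.72 ± 0.15 (camera adjusted p = 1.92e-05; adjusted p = 0.188 with an estimated correlation). Of 20 cholesterol synthesis genes 6 were lower (11 adjusted over the list alone), with HMGCS1 at -0.83 ± 0.15 and STARD4 at -0.53 ± 0.06 (camera adjusted p = 0.000127; adjusted p = 0.129 with an estimated correlation). HIF1 targets were lower (3 of 20, 8 adjusted over the list alone; camera adjusted p = 0.00140; adjusted p = 0.188 with an estimated correlation), and RPL28 (0.38 ± 0.07) led 3 of 31 cytosolic ribosomal proteins that were higher (6 adjusted over the list alone; camera adjusted p = 0.000116; adjusted p = 0.444 with an estimated correlation). XBP1 (-0.32 ± 0.06) was among 4 of 18 endoplasmic reticulum chaperones that were lower (4 also adjusted over the list alone; camera adjusted p = 0.00975; adjusted p = 0.444 with an estimated correlation). PDK4 was the single call of 14 pyruvate dehydrogenase genes (5 lower adjusted over the list alone; camera adjusted p = 0.0201; adjusted p = 0.482 with an estimated correlation). The chaperone and pyruvate dehydrogenase shifts did not pass without si-FAM210B replicate 1 (adjusted p = 0.0513 and 0.0634), after quantile normalization (0.0542 and 0.0709) or cyclic loess (0.0967 and 0.0819) or under a stricter level filter (0.143 and 0.418), the latter also not without both deviating arrays (0.0537), and GDF15 and XBP1 lost their call when 1 or more arrays were left out. The other 26 lists did not pass, among them replication, mitosis (0.522) and NRF2 targets (0.452). Without the deviating pair, replication (adjusted p = 0.0179, 12 higher and 1 lower) and the proteasome (0.0361, 8 higher) passed upward. By fry, interferon-stimulated genes (adjusted p = 0.00066) and apoptosis regulators (0.00463) passed, and endoplasmic reticulum chaperones (0.0531) did not. The median lay over 0 and the test down for complex I, heme and iron, and inflammatory genes.

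si-FAM210B and si-UQCRC2 cells shared many calls in the same direction. Among the genes named above, GREM1 (1.70 and 1.08 in si-FAM210B and si-UQCRC2), STC1 (1.39 and 1.25), TAGLN (1.18 and 0.68) and SPARC (1.03 and 0.56) rose in both, and CYP4F11 (-1.07 and -0.77) and HGD (-0.94 and -0.64) fell in both. Of the calls, 150 genes were higher in both, where independent lists would share 13.4, and 61 were lower in both, where 8.04 would be shared. Opposite calls numbered 4 (6.40 for independent lists) with higher signal in si-FAM210B and 21 (16.8) with higher signal in si-UQCRC2. In 100 simulations without any effect against the same controls, no call was shared, but few calls can arise without effects, so this count does not measure what the shared controls add. Part of the excess of the 211 shared calls may come from the shared controls, which are too few to split. Across genes, which are not independent replicates, the fold changes correlated with r = 0.264 and rho = 0.230, below the simulated mean r of 0.404 (range -0.867 to 0.983). The observed r was 0.446 without control replicate 3 and 0.467 without both deviating arrays, for which no simulation was run. The covariance was 0.00757 against a simulated mean of 0.00477, and 26 of 100 simulations reached it. Without control replicate 3 the observed covariance was 0.0156. Shared calls numbered 1176 without both deviating arrays, 444 without si-FAM210B replicate 1 and 78 without control replicate 2. An F test over the 3 groups called 1849 genes.

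**Figure D4:**
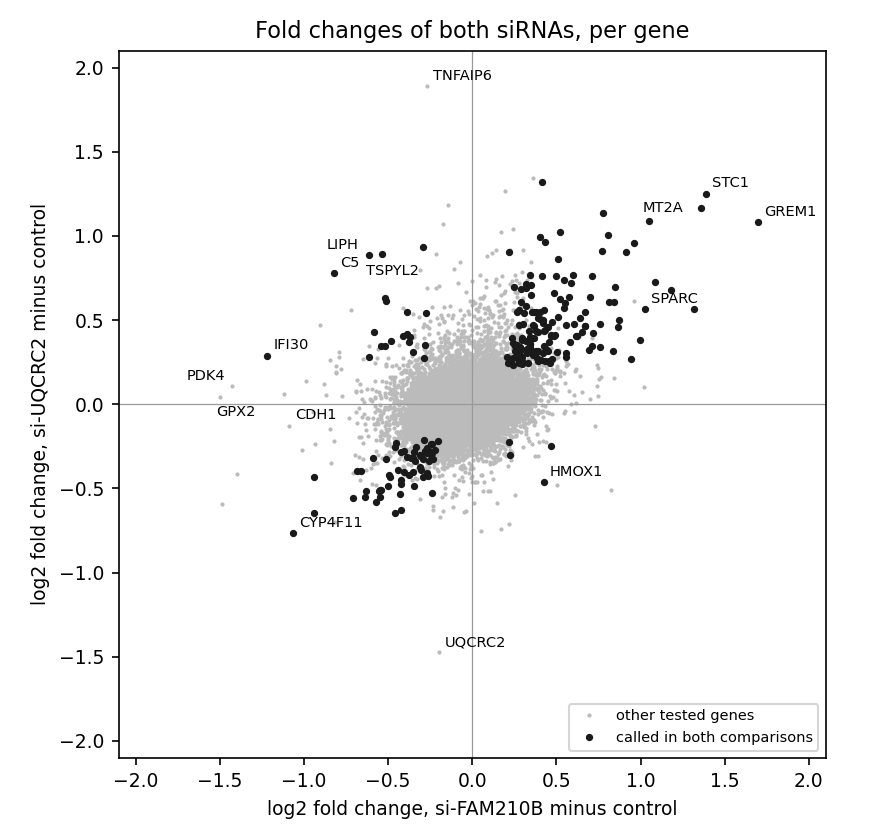
Each point is 1 of the 15964 tested genes, with the log2 fold change of si-FAM210B minus control on the x axis and of si-UQCRC2 minus control on the y axis. Black points were called in both comparisons, 150 higher and 61 lower in both, 25 in opposite directions. UQCRC2 lies alone at the bottom, and PDK4, GPX2 and CDH1 lie far to the left near 0 on the y axis.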

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

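The tests of swapped or mixed arrays, of small RNAs, of a signal floor, of the effect of the deviating array on FAM210B and of the covariance from shared controls were chosen only after the result was seen. The floor test and the shared control test replaced earlier ones, as stated with each, and the mixture test was widened from the genes of at least 2-fold to all called genes.

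IFI30 differed by -1.51 between the siRNAs, having fallen by 1.22 in si-FAM210B and risen by 0.29 in si-UQCRC2. C5 differed by -1.60, having fallen by 0.82 in si-FAM210B and risen by 0.78 in si-UQCRC2. LIPH differed by -1.50 (-0.61 and 0.88) and TSPYL2 by -1.42 (-0.53 and 0.89). HMOX1 differed by 0.88, having risen by 0.42 in si-FAM210B and fallen by 0.46 in si-UQCRC2. These 5 are the genes among the largest changes named for any comparison whose changes were called in opposite directions and whose difference was called too. The integrated stress response list shifted in opposite directions, with a median difference of -0.24, but neither shift nor the difference passed with an estimated correlation (adjusted p = 0.443 in si-FAM210B, 0.308 in si-UQCRC2 and 0.188). The si-FAM210B shift did not pass after quantile normalization (0.0673), after cyclic loess (0.138) or under a stricter level filter (0.147) either. Rows without a single gene symbol lay outside the named genes, and of 16901 such rows 62 were higher and 126 lower than control in si-FAM210B, and 63 higher and 19 lower in si-UQCRC2. Called rows made up 1.11% and 0.485% of them, against 6.28% and 4.46% of the named genes. The largest log2 fold change of these called rows was 2.17 in si-FAM210B, above that of any named gene, and 1.45 in si-UQCRC2.

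si-FAM210B replicate 1 and control replicate 3 deviated from their groups in the same way (r = 0.742 across genes). Swapped labels are argued against, since on the 3889 genes called without both arrays control replicate 3 lay at 0.375 of the way from control to si-FAM210B (bootstrap interval 0.352 to 0.397) and si-FAM210B replicate 1 at 1.32. Intensity-dependent scaling is argued against too, since cyclic loess left the correlation at 0.726. A mixture of si-FAM210B RNA into control replicate 3 needs 1 share for all genes. That array lay at 0.610 (bootstrap interval 0.562 to 0.662) on the 973 called genes with the smallest changes and at 0.255 (0.225 to 0.285) on the 972 with the largest. A mixture also leaves si-FAM210B replicate 1 (1.36 on all called genes by this measure, 1.33 to 1.40) unexplained. The 22 genes of at least 2-fold, used first, were placed by the measure used for swapped labels. On them control replicate 3 lay at 0.0712 (bootstrap interval 0.0126 to 0.140) and si-FAM210B replicate 1 at 1.05. All these bootstrap intervals resample genes, which are not independent, with the arrays held fixed. They leave out the spread between arrays, so they cannot decide whether a mixture contributed. A difference in RNA composition or labelling stays open as well, because small RNA rows exceeded level-matched protein-coding rows by 0.216 ± 0.0583 (SE) in si-FAM210B replicate 1 and by 0.134 ± 0.0407 in control replicate 3. The design names no condition shared by these 2 arrays, so no biological explanation was tested.

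FAM210B fell little in the si-FAM210B arrays. Signals of this level could fall, since TM4SF20, with a similar control level, fell by 1.49 ± 0.203 (SE), 1 of 7 such genes that fell by over 0.5 plus 2 SE. The first criterion counted for a floor when fewer than 5 of the 2152 genes of this level fell by at least 1, and with 2 such genes its result was in favour of the floor. It was replaced because 9 genes of any level were called at that size in si-FAM210B, so few could be found at 1 level. Those 2 falls were known when the replacement was written, so its outcome was fixed and it cannot exclude a floor. The deviating array did not hide a strong fall either, since FAM210B differed by -0.261 without both arrays (95% interval -0.403 to -0.119). Signal of this row from other transcripts, a transcript that recovered by 72 h and a weak knockdown, which is the biological reading the design allows, stay open and untested. The changes of other genes in si-FAM210B cells therefore cannot be assigned to loss of FAM210B from these arrays. Other effects of its siRNA mixture, whose sequences were not used here, were not tested.

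Both siRNAs shared 211 calls in the same direction. The deviating control array was not needed for an overlap of about this size, since 180 calls were shared without it (19.6 for independent lists). Both comparisons still share the other control arrays, so 19.6 is not the count expected if that array were the cause. Shared control arrays cannot be told apart from other causes, since 26 of 100 simulations without effects reached the observed covariance of the fold changes (0.00757, simulated mean 0.00477) and 3 control arrays are too few to split. The covariance rose to 0.0156 without control replicate 3, a fit that was not simulated. The earlier test compared the number of shared calls with those simulations, in which few calls can arise, so its outcome was fixed. Lower cell cycle signal stays open as well for the shared lower calls. Of these, 11.5% (7 of 61, 95% exact binomial interval 4.74% to 22.2%) belonged to the replication, mitosis and histone lists, against 0.695% of all tested genes. The interval treats these genes as independent, which they are not. The 150 shared higher calls were not part of this check. A response to siRNA that either sequence mixture causes may also stay open beside a response shared by loss of either protein, since the sequences were not used here and neither was tested.

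Other divisions of the arrays were refitted. For si-FAM210B against control, the real division gave 1002 genes and the highest other gave 1064, so 2 of 10 reached the real count. That other division set si-FAM210B replicates 1 and 3 with control replicate 3 against the rest, which follows the deviating arrays and points to a structure of the samples. Without both arrays the real division gave 3889, but no other division of the remaining arrays was refitted. That count therefore does not answer the check. For si-UQCRC2 against control the values were 712 and 0 (1 of 10), and for si-FAM210B against si-UQCRC2 1561 and 0 (1 of 10). With 10 divisions no share under 0.05 can be reached in these 3 comparisons. For the F test over the 3 groups, 1 of 100 divisions, the real one, reached 1849 genes and the highest other gave 277. That share is under 0.05 and argues against chance for a difference somewhere among the 3 groups. The division with 277 also kept the 3 si-UQCRC2 arrays together. The F test therefore does not answer the check for si-FAM210B against control.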

How the results depend on the processing

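Cyclic loess and the fit without both deviating arrays were chosen after seeing the data. No called list, and none of the 84, 77 and 108 called genes that the naming rule took, changed direction under the alternatives run. Over the 3 comparisons together, however, 78 of these genes lost their call with median centring. With the replicate number as a block 87 lost it, and with only the groups compared 67. The proteasome list, not called between the siRNAs, was called higher in si-FAM210B without both arrays and without si-FAM210B replicate 1 alone (median 0.0886 in each), which ties it to that array, and had a median of -0.117 without replicate 2. Counts in the order si-FAM210B against control, si-UQCRC2 against control and si-FAM210B against si-UQCRC2 were 3889, 2736 and 3835 without both arrays, 7018, 4145 and 7002 with array weights, 227, 1449 and 1040 with only the groups compared, and 134, 119 and 209 at a minimum of 1.5-fold, which follows from its construction. Genes differing among the 3 groups numbered 5495 without both arrays and 9142 with weights, and shared calls 1176 and 1950. Array weights were estimated gene by gene because the default estimate did not converge, and ranged from 0.0933 for si-FAM210B replicate 1 to 3.07 for control replicate 2. The FAM210B change passed without both arrays (-0.26) and with weights (-0.23). Median centring left 559 calls in si-FAM210B and 113 shared calls. With the estimated correlation 0, 2 and 0 lists shifted, fry passed 16, 16 and 11, and the stricter level filter left 10 lists in si-FAM210B; apart from the fits with fewer samples or genes, the cause was not tested. The replicate number as a block gave 409, 342 and 798 genes, 865 over the 3 groups and 94 shared calls, and the inflammatory list in si-FAM210B did not pass (adjusted p = 0.0573), but deviations of same-numbered arrays correlated from -0.584 to 0.512, and si-FAM210B replicate 1 correlated best with control replicate 3 (0.742), so the numbers do not pair the arrays. With each array left out, counts ranged from 306 to 1975, 249 to 1654 and 505 to 3280, genes over the 3 groups from 729 to 2778, shared calls from 78 to 444, and lists from 14 to 17, 13 to 18 and 10 to 12. The FAM210B change ranged from -0.279 to -0.0912 (without si-FAM210B replicate 2) and that of UQCRC2 from -1.54 to -1.41. Of the named genes, 45 of 84, 43 of 77 and 59 of 108 kept their call with each array left out. Scaling moved the median group difference by at most -0.0835. Signal over background was not used here, so weak genes are limited by an unknown floor.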

Other observations

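These 3 lists and the genes in this part were chosen only after their values were seen, so their tests are not independent evidence. The list p-values in this part were adjusted over these 3 lists alone, not together with the fixed lists. Lists chosen for genes already seen to change can also pass because of that choice. Their adjusted p-values therefore cannot be compared with those of the fixed lists, with either correlation. Metallothioneins, which bind zinc and copper, shifted up as a list with both siRNAs. Of 10 tested, 5 rose in si-FAM210B (camera adjusted p = 5e-06; adjusted p = 0.0481 with an estimated correlation) and 4 in si-UQCRC2 (1.69e-08; adjusted p = 0.0315 with an estimated correlation). MT1F read 0.81 and 1.01 and MT1X 0.41 and 0.76, but these paralogs are nearly identical, so which gene carries the signal is uncertain. The list of contractile and focal adhesion genes shifted up as well. Of 27 tested, 11 rose and PDLIM5 fell in si-FAM210B (camera adjusted p = 3.93e-12; adjusted p = 0.00352 with an estimated correlation), among them MYL9 (0.61 ± 0.07, SE), NEXN (0.60 ± 0.08) and PARVA (0.49 ± 0.07). In si-UQCRC2 8 rose and MYH10 fell (7.68e-07; adjusted p = 0.0193 with an estimated correlation). In the fit without the deviating pair, 23 rose and 1 fell in si-FAM210B, and 12 rose and 2 fell in si-UQCRC2.

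The list of proteins typical of liver shifted down in si-FAM210B. Of 9 tested, 5 fell and AMBP rose (camera adjusted p = 0.00154; adjusted p = 0.0481 with an estimated correlation). The lactonase PON3 (-0.94 ± 0.12), the urea cycle enzyme CPS1 (-0.93 ± 0.12), HGD, which degrades homogentisate (-0.94 ± 0.10), the fibrinogen chain FGA (-0.84 ± 0.10) and complement C5 fell. In si-UQCRC2 the list did not shift (camera adjusted p = 0.570), HGD fell and C5 rose. The difference between the siRNAs passed camera (adjusted p = 0.00797) but not with an estimated correlation (adjusted p = 0.108).

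NAV3, a microtubule-associated protein, rose by 0.96 with each siRNA, and PLEK2 by 0.92 and 0.90. IGFBP7, a secreted binding protein, rose less in si-FAM210B (0.52) than in si-UQCRC2 (1.02). UCP2, a carrier of the inner mitochondrial membrane, fell by 0.58 in si-FAM210B and rose by 0.43 in si-UQCRC2, a difference of -1.01 (limma adjusted p = 3.41e-05).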
